A study of Homo sapiens with 9 samples.

How the data were processed

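Total RNA of 9 samples of the human induced pluripotent stem cell line 414C2 was measured on 1-colour Affymetrix whole-transcript arrays. The samples form 3 groups of 3 biological replicates: sclerotome, the somite derivative that gives rise to the axial skeleton, on day -1, and cartilage pellets on day 28 and day 56 of an induction towards hypertrophic chondrocytes. Per the labels' protocols, pellets were frozen and powdered, RNA was isolated with a column kit for small samples, and amplified and labelled with whole-transcript kits; the same text is given for every sample, the sclerotome samples included. The labels mark the day 56 arrays as a re-analysis of arrays of another deposit, and no dates or batches are given in the sources used here. If each group was its own batch, batch and group cannot be told apart.

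The deposited table holds 28869 probe sets and 1 column per array, with no column of other samples. Its values are log2 values, and the authors made them with RMA (background correction, quantile normalization and summarisation of probes), per the submitters' processing notes; the software, its version and the log base are not given in the sources used here. The base was taken as 2 from the usual output of RMA and from the values, whose largest range within a row was 8.10. The deposited log2 values are centred per probe set, a step that the notes do not describe. In each row between 3 and 6 of the 9 values lie below 0, and in 18009 rows the values next to 0 on either side are equal and opposite within 1e-5. That is the pattern of a median over an even number of arrays, such as these 9 and 3 others, while only 4 rows have a median over the 9 arrays within 1e-6 of 0. Centring keeps differences between arrays and removes the level of each gene. Signal over background could therefore not be assessed, and changes of genes near background are understated by an unknown amount. Array medians lay between -0.01 and 0.02. In arrays, the number of replicates limits the precision; the median standard error of a difference between groups was 0.09 on the log2 scale.

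Probe sets were named with the platform annotation, with symbols updated through gene identifiers in a RefSeq gene table. Of the probe sets, 19310 had 1 gene symbol, 1752 had several and 7807 were not listed in the annotation; only the first kind entered the tests. A further 25 probe sets of sex-linked genes were left out. Of the 19285 used, 31 had no match in the gene table and kept the name of the annotation. The table holds 947 probe sets whose values are identical to those of another probe set, so genes with near-identical copies cannot be told apart.

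The test design was fixed before the data were examined, and it departed from that design in a single rule. The design took, per gene, the probe set with the highest mean, which has no meaning in centred values; the mean of a gene's probe sets was used instead, which concerns 684 genes (3.73%). The filter was kept as designed and asked for the 40th percentile of the table, -0.02, in at least 3 arrays; on centred values it is no filter on low expression, and it removed 5 genes. This left 18348 genes.

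Group means were fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 6 residual and 3.47 prior degrees of freedom. The tests are two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a second count asked also for a change of at least 2-fold. The moderated F test covered the 3 time points together. Errors of fold changes are moderated standard errors (SE) with n = 3 arrays per group. As background, an exact permutation test of 3 against 3 values cannot go below 0.1, so single-gene calls rest on the spread that limma shares across genes. Genes called in both steps of the time course were counted by sign. These counts stand beside the overlap of independent lists and beside 100 simulations of unchanged data that share the day 28 arrays in the same way.

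The 26 gene lists hold 461 genes, of which 419 were measured; they cover skeletal, metabolic, stress, signalling and cell cycle genes, markers of other cell types and housekeeping genes. They were tested against all other genes with camera of limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 78 tests. With a correlation estimated from the residuals no list passed, the lowest adjusted p being 0.058. The 6 residual degrees of freedom give a poor estimate of that correlation. In simulated data with independent genes, a list shifted by 0.5 passed camera with an estimated correlation (adjusted p = 2.58e-05). A raised correlation is not the only reason why no list passed in the real data. For chondrocyte transcription factors on day 28 against day -1 the estimate, -0.012, lay below the preset value. Yet the unadjusted camera p was 0.0026 with the estimate and 2.60e-06 with the preset value. A higher p with an estimated correlation is therefore no measure of how far members vary together. Further reasons were not tested. Members were also counted with p-values adjusted over the list alone. The genes named were set by rule: per comparison the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of one group all lie above the 3 of the other, up to 2 called members per list and direction, 15 key genes whatever their values, and 5 genes for each sign combination of the steps. List members named beyond this rule were chosen after their values were seen.

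The fits were tested on simulated data with the spread of the 18348 genes and 50 genes changed at each of 4 sizes, for the comparison of day 28 with day -1. They recovered 38 of 50 genes (76%) changed by 0.5, 49 of 50 (98%) changed by 1, and all 50 at 2 and at 4 on the log2 scale, with 9 false calls among 196. The simulated genes were independent and had the same spread in every group. In the real comparison far more genes, 9684, were called. These shares therefore test the code and do not give the recovery or the false calls of the real fits.

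Alternatives tried were no filter and a filter at the 60th percentile, repeated quantile normalization, median centring of arrays, an intensity trend with a robust prior, array weights, fits of only the 6 arrays compared, the replicate number as a block, each array left out in turn, a test against a 2-fold change, and the estimated correlation for lists. Added after seeing the data were the highest-mean and the largest-SD probe set, the genes with the larger SD, protein-coding genes only, and the fit without replicate 1 of each group. On centred values the trend runs on means that are no intensities, and the repeated quantile normalization forces an equal spread on arrays whose standard deviations are 0.54 to 0.55 on day -1 and 0.33 to 0.34 on day 28.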

Results

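Expression was profiled in 3 groups of the 414C2 line, a human induced pluripotent stem cell line, with 3 arrays each: sclerotome on day -1 of induction, and cartilage pellets, small 3-dimensional cultures, on day 28 and day 56. The time course asks how expression changes while sclerotome turns to cartilage and the cartilage cells proceed towards hypertrophy, the enlarged state that precedes mineralization in the growth plate. All values are log2 values centred per probe set, so differences between groups are given and levels are not. Within groups, arrays correlated across probe sets with r between 0.943 and 0.966 on day -1, 0.842 and 0.908 on day 28, and 0.812 and 0.907 on day 56. Between day 28 and day 56 r lay between 0.200 and 0.367, and between day -1 and the later days between -0.481 and -0.374; probe sets are not independent, and centring lowers correlations between groups. In each group replicate 1 had the lowest mean r with the other arrays, 0.945 on day -1, 0.851 on day 28 and 0.821 on day 56.

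**Figure D1:**
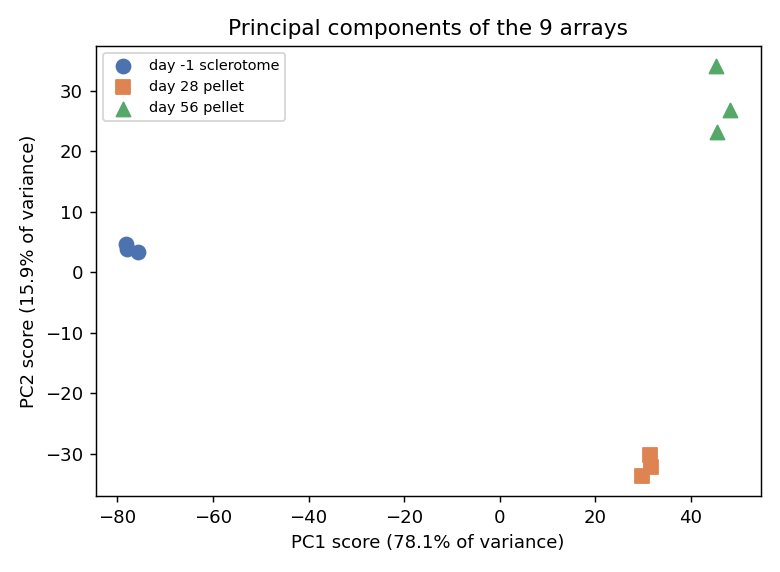
Scores of the 9 arrays on the first and second principal component of 18348 genes; each point is an array and colours and shapes mark the groups. PC1 holds 78.1% of the variance and separates day -1 from both pellet groups, and PC2 holds 15.9% and separates day 28 from day 56.

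From day -1 to day 28, 21 of 22 cartilage matrix genes rose and 1 fell, and all 31 cell cycle genes fell. Camera gave these lists adjusted p = 6.60e-16 and 4.87e-23, and adjusted p = 0.12 and 0.058 with an estimated correlation. EPYC, a small proteoglycan of cartilage, rose by 7.90 ± 0.30 (SE, 239-fold), and ACAN, the core protein of the main cartilage proteoglycan, by 6.83 ± 0.09 (114-fold). COL2A1, the main cartilage collagen, rose by 3.77 ± 0.13 (13.7-fold, adjusted p = 1.06e-08), and SOX9, the transcription factor required for cartilage formation, by 0.94 ± 0.09. The proliferation marker MKI67 fell by 3.90 ± 0.11 and PAX9, a sclerotome transcription factor, fell by 3.50 ± 0.12. PAX1, another sclerotome factor, did not pass the test (0.75 ± 0.33, adjusted p = 0.085); without replicate 1 of day -1 the difference was 1.20 (adjusted p = 0.000656), and without replicate 1 of all groups it was 1.01 (adjusted p = 0.000306). PAX1 passed in 6 alternatives in all, among them quantile normalization repeated (0.012), array weights (0.040) and the genes with the larger SD (0.038). Of 18348 genes, 4352 were higher and 5332 lower on day 28, and 2582 changed at least 2-fold, 1098 up and 1484 down.

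The other largest rises were those of CLEC3A (7.39), a lectin found in cartilage, the mineralization inhibitor MGP (6.89), the sphingomyelinase SMPD3 (6.69), FGFBP2 (6.65), the matrilins MATN3 (5.76) and MATN1 (5.67), the actin-severing protein SCIN (5.70), and UCMA (5.64), a secreted protein of cartilage. The largest falls were those of NNAT (-5.39), the linker histone gene H1-5 (-5.19), IGFBP5 (-5.16), the histone gene H3C2 (-4.62), the apelin receptor APLNR (-4.62), the nuclear receptor NR6A1 (-4.58), CENPF (-4.49) and KIF20A (-4.45) of the mitotic apparatus, the proteoglycan VCAN (-4.44) and DTL (-4.44). For these 20 genes, adjusted p lay between 1.22e-11 for SMPD3 and 1.75e-05 for NNAT.

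The cartilage matrix gene that fell was CYTL1, a secreted protein gene, at -0.37 ± 0.11, whose call ended without replicate 1 (adjusted p = 0.056) or without replicate 2 of day -1 (adjusted p = 0.050). Among 16 hypertrophic chondrocyte genes 15 rose and none fell (adjusted p = 3.27e-10; adjusted p = 0.058 with an estimated correlation). COL10A1, the collagen of hypertrophic cartilage, rose by 5.08 ± 0.18, ALPL, the alkaline phosphatase of mineralizing cells, by 4.54 ± 0.12, and IHH, the hedgehog ligand of prehypertrophic cells, by 2.44 ± 0.18. PTH1R, the receptor of parathyroid hormone-related protein, rose by 3.28 ± 0.11, the collagenase gene MMP13 by 2.94 ± 0.29 and IBSP, a bone matrix protein gene, by 3.71 ± 0.38. The remaining member, SPP1 (osteopontin), was at -0.02 ± 0.27 (adjusted p = 0.96). With quantile normalization repeated, IBSP was at 0.99 (adjusted p = 0.051) and MMP13 at 1.06 (adjusted p = 0.058). Of 12 chondrocyte transcription factors, 10 rose and 1 fell (adjusted p = 2.02e-05; adjusted p = 0.058 with an estimated correlation), led by MEF2C (4.55) and RUNX2 (4.03), which both drive hypertrophy, while ZNF219 was at -1.42. Of 20 osteoblast and mineralization genes, 14 rose and 1 fell (adjusted p = 2.27e-05; adjusted p = 0.14 with an estimated correlation). The phosphatase gene PHOSPHO1 rose by 5.05 and SP7, a transcription factor of osteoblasts, by 2.14, while the type I collagen gene COL1A2 was at -1.69 ± 0.32. Of the measured members, 5 transcription factors and 3 osteoblast genes (ALPL, IBSP and SPP1) are also in the hypertrophic list. Articular cartilage genes were not called as a list, with 5 of 7 higher and none lower (adjusted p = 0.11; 0.047 without replicate 1 of all groups); ABI3BP rose most, by 3.49.

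Changes of the 31 cell cycle genes lay between -4.49 and -1.08. In the sclerotome and paraxial mesoderm list 9 of 18 genes fell and none rose (adjusted p = 0.033; adjusted p = 0.19 with an estimated correlation), among them TBX18 (-3.06 ± 0.11). This list was not called with the stricter filter (adjusted p = 0.059), with quantile normalization repeated (0.084) or among the genes with the larger SD (0.055). In the pluripotency list 6 of 14 genes fell and 1 rose (adjusted p = 0.035; adjusted p = 0.19 with an estimated correlation). The genes that moved most were LIN28A (-4.13), which blocks maturation of let-7 microRNAs, and SALL4 (-4.01), which are also active in early embryonic progenitors, and the riser was UTF1 at 0.25.

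Of 22 genes of hypoxia and glycolysis, 20 rose and 1 fell (adjusted p = 3.27e-10; adjusted p = 0.19 with an estimated correlation). Carbonic anhydrase CA12 rose by 3.15 ± 0.33 and the mitophagy gene BNIP3 by 3.08 ± 0.07. The fall was that of KDM3A, a demethylase gene (-0.41 ± 0.12), whose call ended without replicate 2 of day -1 (adjusted p = 0.053) or replicate 3 of day 28 (adjusted p = 0.055). Of 22 genes of oxidative phosphorylation, 14 fell and none rose (adjusted p = 0.018; adjusted p = 0.47 with an estimated correlation), with COX7B at -1.19 ± 0.25 and NDUFS3 at -0.87 ± 0.13. The call of this list ended with the stricter filter (adjusted p = 0.051) and among the genes with the larger SD (0.14). In the unfolded protein and amino acid response 16 of 22 genes rose and 1 fell (adjusted p = 2.38e-05; adjusted p = 0.14 with an estimated correlation). CHAC1, which degrades glutathione, rose by 2.74 and the stress transcription factor DDIT3 by 2.08; the fall was SDF2L1 (-0.31).

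Of 22 BMP and TGF-beta pathway genes, 14 rose and 3 fell (adjusted p = 2.98e-05; adjusted p = 0.19 with an estimated correlation). The leading members were the BMP antagonists GREM1 (5.01 ± 0.19) and CHRDL2 (4.94 ± 0.12), which inhibit the pathway the list is named for. The falls included CHRDL1 (-1.28 ± 0.42, adjusted p = 0.026), also a BMP antagonist, and BMP7 (-1.14). The call of CHRDL1 ended without replicates 2 or 3 of day -1 (adjusted p = 0.099 and 0.091) or of day 28 (0.091 and 0.075). Of 18 matrix proteases and inhibitors, 10 rose and 1 fell (adjusted p = 0.0074; adjusted p = 0.23 with an estimated correlation), the largest rise being that of the protease inhibitor gene TIMP4 (4.85) and the fall that of ADAMTS9 (-1.30). Immediate early and heat shock genes, which respond to handling as well as to signals, had 7 of 13 members higher and 2 lower (adjusted p = 0.049; adjusted p = 0.52 with an estimated correlation), among them ZFP36 (1.99) and FOS (1.92). Without replicate 1 of day -1 the adjusted p was 0.081, and without replicate 1 or 3 of day 28 it was 0.055 and 0.058. It was 0.050 without replicate 1 of day 56, and the call ended in 8 alternatives in all besides the estimated correlation, with adjusted p up to 0.087.

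The remaining lists were not called for this step. Counts of higher and lower genes were 4 and 3 of 14 for the Hedgehog pathway, 9 and 8 of 22 for the WNT pathway, 5 and 2 of 7 for the thyroid hormone axis, 1 and 4 of 11 for sterol and fatty acid synthesis, and 3 and 1 of 27 for HOX genes. The sterol list (adjusted p = 0.14) passed without replicate 1 of day -1 (adjusted p = 0.044) and without replicate 1 of all groups (0.010). They were 3 and 2 of 10 for housekeeping genes, with B2M at 1.34 and ACTB at -0.97. Among markers of other cell types they were 3 and 5 of 15 for neural, 5 and 1 of 18 for skeletal muscle, 5 and 7 of 16 for tendon and fibroblast, 6 and 3 of 18 for endothelial and blood, 4 and 0 of 10 for adipocyte, and 3 and 0 of 9 for epithelial genes. The tendon and fibroblast genes moved apart, with decorin (DCN) at 4.51 ± 0.34, the tendon factor MKX at 3.84 ± 0.11 and ACTA2 at -2.48 ± 0.18. The WNT antagonist FRZB rose by 2.67 while SFRP1, another antagonist, was at -3.16. Counts adjusted over the list alone differed from these in 7 lists, higher and lower respectively: sclerotome 1 and 9, Hedgehog 6 and 3, transcription factors 11 and 1, HOX 0 and 1, BMP 14 and 4, muscle 3 and 1, endothelial and blood 7 and 3. The median and mean of the HOX list (0.08 and -0.01) and of the WNT list (0.14 and -0.03) differed in sign, and camera placed both lists up.

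**Figure D2:**
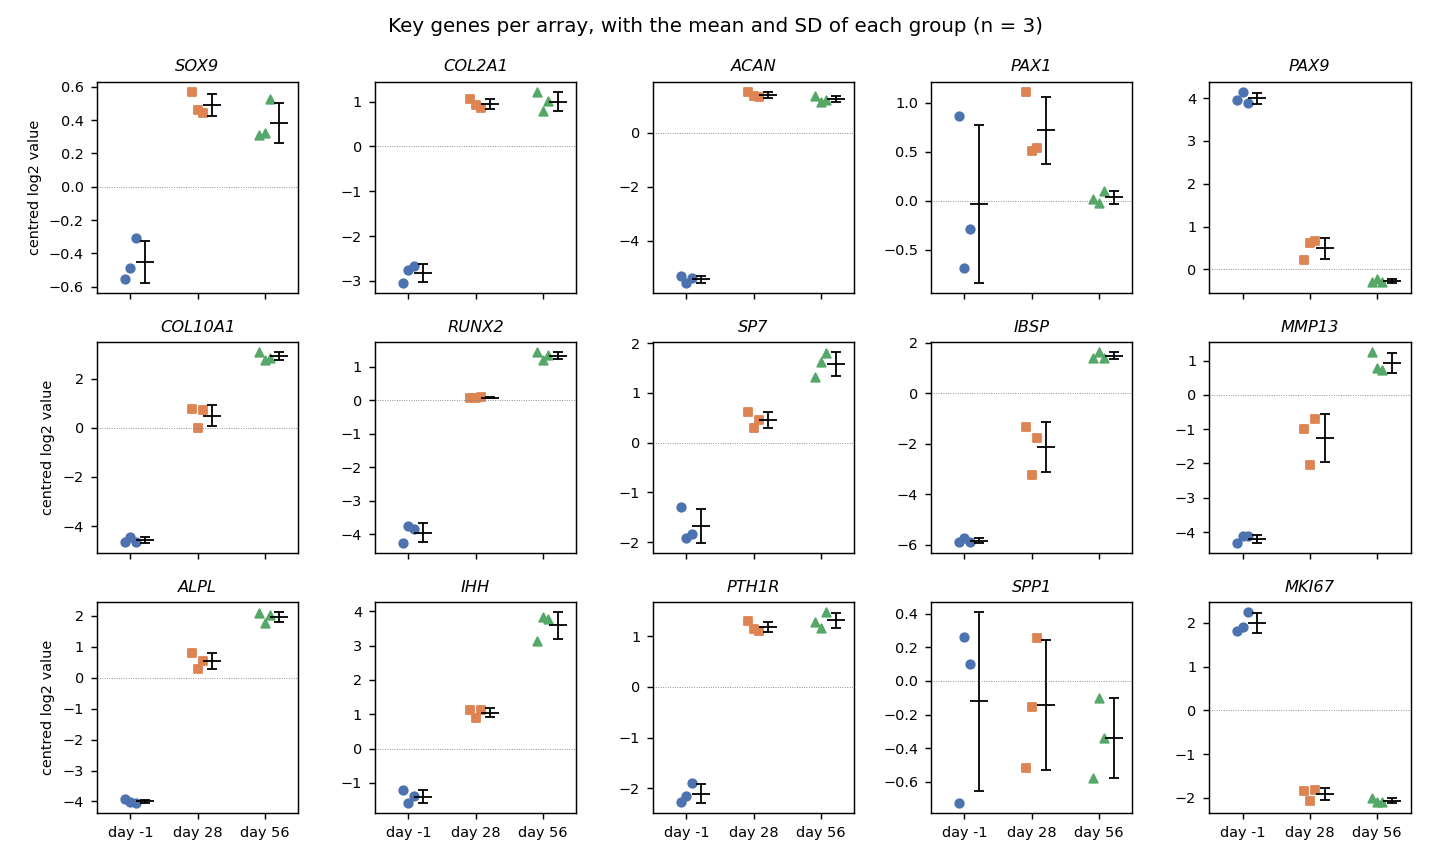
Centred log2 values (vertical axes, scaled per gene) of the 15 key genes in the 3 arrays of each group; points are arrays and black bars give the group mean and SD (n = 3). COL2A1 and ACAN lie apart on day -1 and overlap between day 28 and day 56. COL10A1, RUNX2, ALPL and IHH are highest on day 56. Between day 28 and day 56, ACAN, MKI67 and SOX9 were called only with quantile normalization repeated, which forces an equal spread on the arrays.

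From day 28 to day 56, 10 of 16 hypertrophic genes rose and 6 did not pass, and of 22 cartilage matrix genes 10 fell and 2 rose. Camera gave these lists adjusted p = 3.47e-05 and 5.04e-05, and adjusted p = 0.14 and 0.33 with an estimated correlation. COL10A1 rose by 2.40 ± 0.18 (5.29-fold, adjusted p = 1.54e-05), IBSP by 3.61 ± 0.38 (12.2-fold), IHH by 2.55 ± 0.18, MMP13 by 2.17 ± 0.29, ALPL by 1.43 ± 0.12, RUNX2 by 1.25 ± 0.12 and SP7 by 1.11 ± 0.18. UCMA fell by 5.62 ± 0.12, close to its whole rise before day 28, and EPYC fell by 2.41 ± 0.30. COL2A1 (0.06 ± 0.13, adjusted p = 0.78), ACAN (-0.16 ± 0.09, adjusted p = 0.20) and SOX9 (-0.11 ± 0.09, adjusted p = 0.39) did not pass the test, nor did PTH1R (0.13), PAX1 (-0.69), SPP1 (-0.20) and MKI67 (-0.16). With quantile normalization repeated, ACAN was at -0.51 (adjusted p = 0.0013), SOX9 at -0.31 (adjusted p = 0.016), and MKI67 turned to 0.51 (adjusted p = 0.0082). PAX1 passed in the fit without replicate 1 of day -1 (adjusted p = 0.013), without replicate 1 of all groups (-0.48, 0.023), with quantile normalization repeated (-0.95, 0.023) and in the fit of only the 6 arrays compared (0.016). In all, 3668 genes were higher and 2477 lower on day 56, and 810 changed at least 2-fold, 481 up and 329 down.

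The other largest rises were those of the proteoglycan SPOCK2 (4.22 ± 0.24), the tetraspanin TSPAN8 (4.06 ± 0.33), GPR158 (3.90), the immune checkpoint ligand VTCN1 (3.69), the leukotriene receptor CYSLTR1 (3.53), the retinaldehyde dehydrogenase ALDH1A1 (3.28), the surface glycoprotein CD24 (3.25), carbonic anhydrase CA2 (3.19) and the phospholipase PLA2G10 (3.16). The other largest falls were those of the BMP antagonist GREM1 (-4.66 ± 0.19), the glypican GPC3 (-4.12), MFAP4 (-3.98) and the imprinted genes DLK1 (-3.97) and MEST (-3.78). They were followed by SRPX (-3.32), FIBIN (-3.06), the small nucleolar RNA SNORA22 (-3.03) and ATP1B2 (-3.02). Day 56 arrays came from another deposit, and a batch difference would enter all of these values.

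Among the hypertrophic genes the channel protein gene PANX3 also rose, by 2.83 ± 0.31. The falls of cartilage matrix genes included CHAD (-2.15), MATN4 (-1.84) and CNMD (-1.66), and the rises were PRELP (0.86 ± 0.26) and SNORC (0.37 ± 0.11). The rise of PRELP was not called without replicates 2 or 3 of day 28 (adjusted p = 0.091 and 0.081) or 1 or 3 of day 56 (0.067 and 0.069). The rise of SNORC was not called without replicates 1 or 2 of day 28 (0.071 and 0.074) or 3 of day 56 (0.068), and its difference was 0.018 with quantile normalization repeated (adjusted p = 0.92). Of 16 tendon and fibroblast genes, 7 fell and 1 rose (adjusted p = 0.0017; adjusted p = 0.30 with an estimated correlation): POSTN was at -2.80 ± 0.66, THY1 at -2.69 ± 0.19, DCN at -2.54 and LUM at -2.23. The riser was ACTA2 (0.56 ± 0.18), which was not called in the fit of only the 6 arrays compared (adjusted p = 0.056). Nor was it called without replicate 3 of day -1 (0.060), replicates 2 or 3 of day 28 (0.146 and 0.137) or any replicate of day 56 (0.061 to 0.102).

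All 11 measured genes of sterol and fatty acid synthesis fell (adjusted p = 6.39e-06; adjusted p = 0.34 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, was at -1.55 ± 0.30 and DHCR7, the last step of cholesterol synthesis, at -1.06 ± 0.20; the smallest change was that of the regulator SREBF2 at -0.40. Of 27 HOX genes, 12 rose and HOXA2 fell (adjusted p = 0.015; adjusted p = 0.52 with an estimated correlation); HOXB2 rose by 0.92 ± 0.19, and HOXA2 was at -1.05. The call of the HOX list ended among the genes with the larger SD (adjusted p = 0.064). Genes of the hypoxia and glycolysis list were 11 higher and 3 lower of 22 (adjusted p = 0.11), with EGLN3, which marks hypoxia-inducible factors for degradation, at 2.18. That list passed without replicate 1 of day 28 (adjusted p = 0.013) and without replicate 1 of all groups (0.042).

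Other lists showed opposed members. In the Hedgehog pathway IHH rose while the pathway's target genes PTCH1 (-2.55 ± 0.30) and HHIP (-2.06 ± 0.30) fell. In that list 3 genes were higher and 6 lower of 14 (adjusted p = 0.080). The adjusted p was 0.044 without replicate 1 of day -1, 0.048 in the fit of only the 6 arrays compared and 0.042 without replicate 1 of all groups. Osteoblast and mineralization genes were 10 higher and 5 lower of 20 (adjusted p = 0.23), with PHOSPHO1 at 1.85 and the peptidase gene PHEX at -2.60. In the BMP and TGF-beta pathway 7 were higher and 5 lower of 22 (adjusted p = 0.97), with the ligand genes BMP7 (2.23) and BMP6 (1.59) higher and the antagonist NOG (-2.33) lower. In the WNT pathway 6 were higher and 3 lower of 22 (adjusted p = 0.97), with WNT11 at 2.32 and SFRP1 at -2.17. Chondrocyte transcription factors were 3 higher and 3 lower of 12 (adjusted p = 0.92), with FOXA2 at 1.21 and SOX5, a partner of SOX9, at -1.40. The unfolded protein and amino acid response list was 12 higher and 5 lower of 22 (adjusted p = 0.053), with SESN2 at 1.53 and the endoplasmic reticulum enzyme gene PDIA4 at -0.88. It passed in 7 alternatives, among them those without replicate 1 of day -1 (adjusted p = 0.044), of day 56 (0.022) or of all groups (0.015).

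Among the remaining lists, higher and lower genes were 2 and 5 of 18 for sclerotome, 0 and 3 of 7 for articular cartilage, 3 and 4 of 31 for cell cycle and 2 and 0 of 14 for pluripotency. They were 4 and 0 of 22 for oxidative phosphorylation, 4 and 2 of 18 for matrix proteases and inhibitors, 3 and 0 of 7 for the thyroid hormone axis, 3 and 2 of 13 for immediate early and heat shock, and 2 and 1 of 10 for housekeeping genes. The cell cycle list was not called (adjusted p = 0.15), with changes between -0.51 and 0.69 and TOP2A at -0.51 ± 0.06. With quantile normalization repeated TOP2A was at 0.035 and the list was called in the other direction (adjusted p = 0.019). Markers of other cell types were 2 and 0 of 15 for neural, 2 and 2 of 18 for skeletal muscle, 0 and 1 of 18 for endothelial and blood, 2 and 0 of 10 for adipocyte and 0 and 0 of 9 for epithelial genes. The largest rises among them were those of PAX6 (3.10 ± 0.26), a transcription factor of eye and brain, and PPARG (1.83 ± 0.15), the fat cell regulator. Adjusted over the list alone, 7 lists gave other counts, higher and lower respectively: sclerotome 3 and 5, HOX 15 and 1, hypoxia 12 and 5, oxidative phosphorylation 3 and 0, unfolded protein response 13 and 5, BMP 7 and 6, adipocyte 1 and 0. Median and mean differed in sign for the BMP list (0.17 and -0.25), oxidative phosphorylation (-0.03 and 0.03), immediate early genes (0.07 and -0.07) and neural genes (-0.01 and 0.17). For skeletal muscle both were above 0 (0.04 and 0.03) while camera placed the list down.

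**Figure D3:**
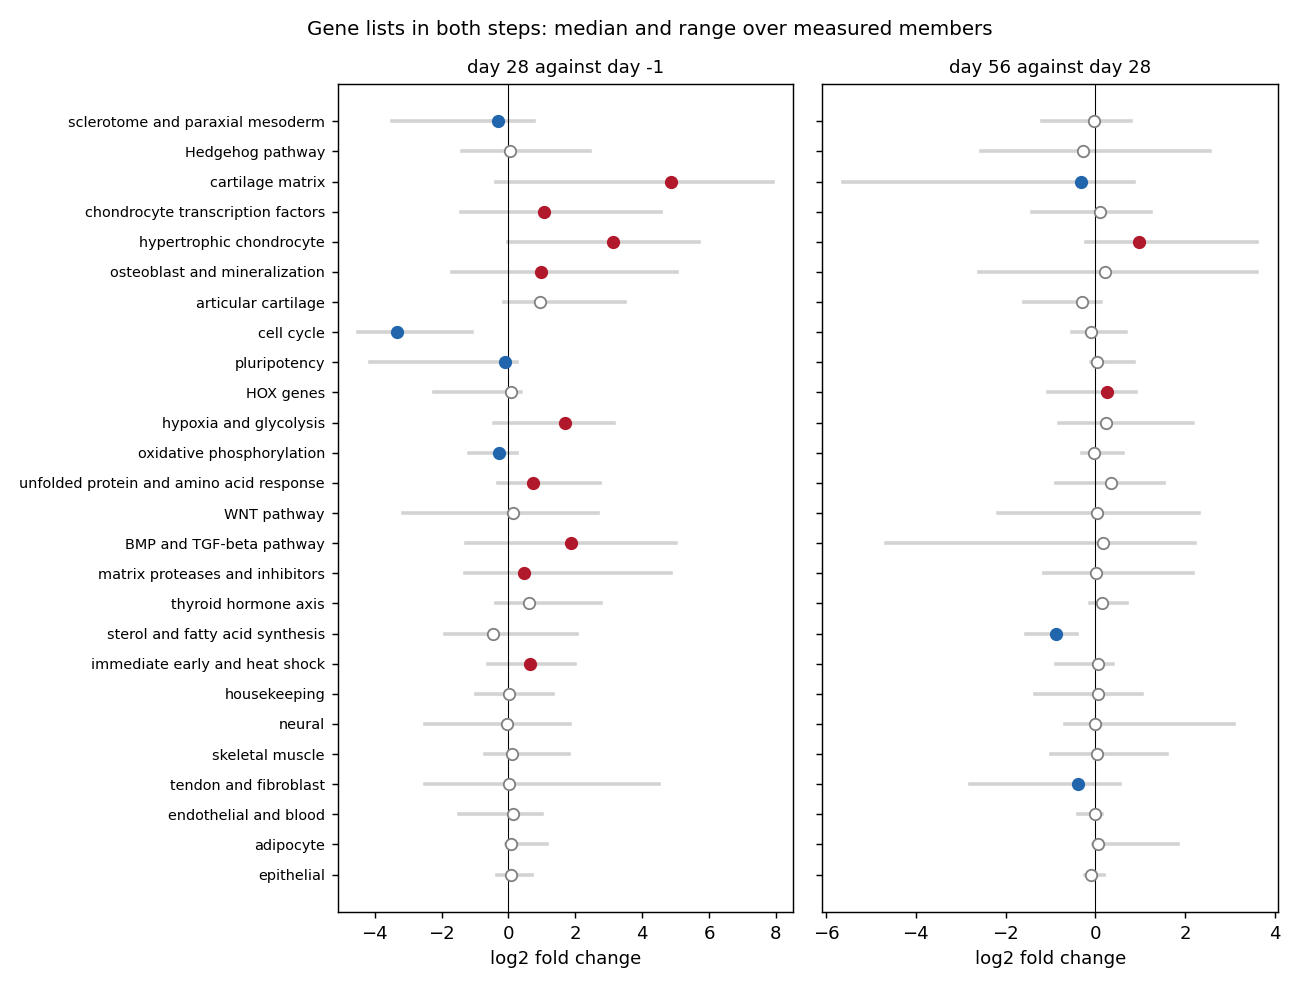
Median log2 fold change (points) and range over measured members (grey lines) of the 26 gene lists in each step, with separate horizontal scales. Filled points are lists with an adjusted p under 0.05 in camera with the preset correlation, red up and blue down; 13 lists were called for day 28 against day -1 and 5 for day 56 against day 28, and none with an estimated correlation.

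Over the whole course, from day -1 to day 56, COL10A1 showed the largest rise (7.48 ± 0.18, 178-fold, adjusted p = 1.25e-09), ahead of IBSP (7.32 ± 0.38), FGFBP2 (7.31), PHOSPHO1 (6.90), SMPD3 (6.90), MGP (6.90), ACAN (6.67), CLEC3A (6.14), the sphingomyelin synthase SGMS2 (6.12) and the small heat shock protein CRYAB (6.07). The largest falls were those of NNAT (-6.60 ± 0.54), VCAN (-6.44), IGFBP5 (-5.97), H1-5 (-5.50), H3C2 (-5.50), cadherin 11 (CDH11, -5.37), SFRP1 (-5.33), H2BC14 (-5.11), CKS2 (-5.06) and the fibrillin FBN2 (-4.92). Of the key genes, ALPL (5.96), RUNX2 (5.28), MMP13 (5.12), IHH (4.99), COL2A1 (3.83), PTH1R (3.41), SP7 (3.26) and SOX9 (0.84) were higher and PAX9 (-4.26) and MKI67 (-4.06) lower. PAX1 (0.07) and SPP1 (-0.22) did not pass. PAX1 was called at 0.52 without replicate 1 of day -1 (adjusted p = 0.043), and without replicate 1 of all groups PAX1 was called at 0.53 (adjusted p = 0.0089) and SPP1 at -0.40 (adjusted p = 0.047). In all, 5158 genes were higher and 5099 lower, with 3000 changed at least 2-fold, 1414 up and 1586 down.

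For this comparison 12 lists were called, 9 up and 3 down, and none with an estimated correlation. Up were cartilage matrix (20 higher, 1 lower of 22; adjusted p = 2.43e-11), hypertrophic chondrocyte (15 and 0 of 16; 3.27e-10), hypoxia and glycolysis (20 and 0 of 22; 1.63e-09), the unfolded protein response (17 and 1 of 22; 2.16e-05), BMP and TGF-beta (16 and 2 of 22; 2.43e-05), and osteoblast and mineralization (13 and 1 of 20; 0.00062). Also up were chondrocyte transcription factors (9 and 3 of 12; 0.0020), HOX genes (14 and 1 of 27; 0.0080) and matrix proteases (8 and 1 of 18; 0.036). Down were cell cycle (0 and 31 of 31; 9.54e-23), sterol and fatty acid synthesis (1 and 10 of 11; 0.0012) and sclerotome (2 and 10 of 18; 0.0083). With an estimated correlation the lowest adjusted p was 0.058, for the hypertrophic and cell cycle lists. The call of the matrix protease list ended without replicate 1 of day 56 (adjusted p = 0.061), and that of the HOX list among the genes with the larger SD (adjusted p = 0.11). Immediate early and heat shock genes (7 and 0 of 13; 0.053) and oxidative phosphorylation (2 and 13 of 22; 0.058) were not called. The immediate early list passed in 9 alternatives (adjusted p between 0.027 and 0.047), 6 of which left out a single array: replicates 2 or 3 of day -1, any replicate of day 28, or replicate 2 of day 56. Oxidative phosphorylation passed in 3 (0.027 to 0.049), among them the fit without replicate 2 of day 56. Pluripotency (0 and 5 of 14; 0.11) passed among the genes with the larger SD (adjusted p = 0.014), and tendon and fibroblast (2 and 8 of 16; 0.17) without replicate 1 of all groups (adjusted p = 0.042). Over the list alone, counts differed for 1 called list, hypoxia and glycolysis, with 20 higher and 1 lower.

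Genes called in both steps show which ones kept moving and which turned back. In both steps 1060 genes rose, against 870 for independent lists; 1093 rose and then fell, against 588; 1372 fell and then rose, against 1066; and 732 fell in both, against 720. The overlap of independent lists is taken over all genes tested, also those that changed in neither step. Every sign combination lies above it, so an excess over it does not show that genes tended to keep moving or to turn back. In simulated data without changes no gene was called in both steps. Adjustment over all genes leaves few calls in such data. The simulation therefore does not measure how often the shared day 28 arrays make changed genes turn back. At least 2-fold in both steps, the counts were 134, 142, 56 and 40. The genes named for each sign combination are ranked by the smaller of their changes in the steps, not by total change. By that rank IBSP (3.71 then 3.61), SERPINI1 (3.11 then 2.83), ALDH1A1 (2.60 then 3.28), CA2 (2.56 then 3.19) and IHH (2.44 then 2.55) led the continued rises. With quantile normalization repeated, CA2 was at 0.65 in the first step (adjusted p = 0.14). UCMA (5.64 then -5.62), GREM1 (5.01 then -4.66), DLK1 (4.75 then -3.97), FIBIN (3.98 then -3.06) and the carboxypeptidase CPZ (3.22 then -2.88) rose and then fell. CD24 (-2.89 then 3.25), COLEC12 (-2.71 then 1.95), CD200 (-2.21 then 2.42), TNFRSF21 (-1.92 then 2.27) and the tight junction gene CLDN1 (-1.85 then 2.12) fell and then rose. CDH11 (-3.52 then -1.85), VCAN (-4.44 then -1.99), SFRP1 (-3.16 then -2.17), the laminin LAMB1 (-2.79 then -1.87) and FBN2 (-2.53 then -2.39) fell in both.

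Across genes, fold changes of the steps correlated with r = -0.06, against a mean of -0.50 in simulations without changes, where the shared day 28 arrays alone set the sign; genes are not independent replicates. The covariance was -0.0249 against -0.00538 simulated, a difference of -0.0195. The 3 shared arrays cannot be divided into groups of at least 2, so part of the count of genes that turned back may come from them. Over the 3 time points together, the moderated F test called 11774 of 18348 genes.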

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

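These counts concern probe sets outside the comparisons by gene, fitted with the same model; this count was not part of the design fixed beforehand. Among 7807 probe sets that the annotation does not list, 180 were at least 2-fold higher on day 28 than on day -1 at an adjusted p under 0.05, with a largest rise of 4.63 on the log2 scale. Between day 28 and day 56, 34 of them were at least 2-fold higher, with a largest rise of 2.45, and at any size 434 were higher and 1133 lower. Among 1752 probe sets assigned to several genes, 71 were at least 2-fold higher on day 28 than on day -1 and 16 on day 56 than on day 28. Of the 18348 genes tested, 1098 and 481 were at least 2-fold higher in these steps. That is a larger share than in either kind of probe set, so the counts above are no excess. What these probe sets measure is not given in the sources used here. No explanation was tested. No test for outlying arrays was run within the groups of 3; array weights, fitted over all 9 arrays, lay between 0.420 for replicate 1 of day 56 and 1.58 for replicate 3 of day 28.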

How the results depend on the processing

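The highest-mean and largest-SD probe set, the genes with the larger SD, protein-coding genes only and the fits without replicate 1 of each group were chosen after seeing the data. Counts at least 2-fold and the F test stayed within 1.5 times their value under every alternative run for them, as did the other counts except those given next. Tested against a change of 2-fold, day 28 against day -1 had 653 genes higher and 818 lower, day 56 against day 28 had 113 and 95, and day 56 against day -1 had 884 and 970, as follows from a stricter null. With quantile normalization repeated, 1705 genes rose and then fell; the cause was not tested. With an estimated correlation 0 lists were called in each comparison, against 13, 5 and 12; at an unadjusted p under 0.05, camera gave 10, 1 and 8 lists. Without replicate 1 of all groups 8 lists were called for day 56 against day 28; the cause was not tested.

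Directions reversed only with quantile normalization repeated: PPARG on day 28 against day -1 (-0.16), and on day 56 against day 28 TOP2A (0.035), MKI67 (0.51) and the cell cycle list relative to other genes (0.24). The forced equal spread of centred values is part of that setting's construction; the cause was not tested further. All other alternatives for named genes and lists kept the direction of any called value. Median fold changes of all genes stayed under 0.1 in every scaling.

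With single arrays left out, higher genes ranged from 3644 to 4588 for day 28 against day -1, 2898 to 3793 for day 56 against day 28 and 4499 to 5148 for day 56 against day -1; lower genes ranged from 4781 to 5553, 2016 to 2606 and 4661 to 5122. Of the genes called, 81.5%, 70.2% and 84.4% were called in the same direction in all 9 such fits. Where an array is left out, its group keeps 2.

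No label says that replicate numbers pair the arrays, and deviations of same-numbered arrays correlated between -0.058 and 0.145. The correlation was above 0.1 in 1 of 9 pairs, and 2 arrays correlated best with their own number in both other groups. Between day 28 and day 56, same-numbered arrays gave 0.145, 0.070 and 0.088, and other pairs lay between -0.240 and 0.213. With 3 arrays per group these values cannot exclude shared culture runs. With the replicate block, 4216 genes were higher and 5236 lower for day 28 against day -1, 3628 and 2437 for day 56 against day 28, and 5007 and 5037 for day 56 against day -1, with 13, 6 and 14 lists called. With it, PAX1 on day 28 against day -1 passed (adjusted p = 0.034), as did the unfolded protein list on day 56 against day 28 (0.032) and, on day 56 against day -1, oxidative phosphorylation (0.048) and immediate early genes (0.037). Levels over background are unknown, so no limit by signal could be given.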

Other observations

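The gene classes in the next paragraph, the classes of small RNA and the neural and epithelial tests were chosen after their values were seen; the other tests were set before the result they measure was seen, on patterns found in the same data. Intervals are 95% bootstrap intervals over genes, which are not independent.

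Of replication-dependent histone genes, on day 28 against day -1, 50 of 61 were lower and 3 higher, with a median of -1.69 (interval -2.25 to -1.46) and an adjusted p of 4.68e-15 in camera (adjusted p = 0.33 with an estimated correlation). Copies of these genes are near-identical, so single members are uncertain. Zinc finger genes of the ZNF series, a large family of transcriptional regulators, had 229 of 438 members lower and 37 higher on day 28, with a median of -0.30 (adjusted p = 1.26e-06; adjusted p = 0.43 with an estimated correlation). Of genes of cytosolic ribosomal proteins, on day 56 against day 28, 39 of 56 were lower and none higher, with a median of -0.39 (adjusted p = 1.30e-13; adjusted p = 0.40 with an estimated correlation), and RPS21 was lowest at -0.97. Of the day 56 arrays replicate 1, which also had the lowest weight (0.420), lay apart with a class median of -0.37, against -0.14 and -0.10; without replicate 1 of all groups 33 were lower and the median was -0.34. Directions of these medians held with median centring and with quantile normalization repeated.

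Small nucleolar RNAs, which guide modification of ribosomal RNA, and spliceosomal RNAs were lower on day 56 than on day 28: 103 of 175 and 16 of 20 fell and none rose, with medians of -0.48 and -0.71, and camera gave the first an adjusted p of 2.27e-24 (adjusted p = 0.22 with an estimated correlation). For small nucleolar RNAs, most of which are cut from introns of host genes, lower levels of host transcripts as a group are argued against. The 62 hosts of 82 of them had a median of -0.0804 (interval -0.17 to 0.02). This is above the bound set at 50% of the small nucleolar RNA median. Of these hosts 18 were lower and 11 higher, and SNHG29 (-1.02), ZFAS1 (-0.94) and SNHG17 (-0.78) fell. Transcription itself was not measured, hosts were assigned by position without regard to strand, and hosts of spliceosomal RNAs were not tested. Lower recovery of short RNA from the day 56 samples stays open. Against day 28 the median of 173 microRNA precursors was -0.07 (upper bound -0.0488), with 31 lower and 3 higher. Camera gave them an adjusted p of 7.62e-05 (adjusted p = 0.40 with an estimated correlation). This met the test as first set, which named that comparison only. The comparison with day -1 was added after that result was seen. There the precursor median was -0.0089 (interval -0.019 to 0.022), with small nucleolar RNAs at -0.30 and spliceosomal RNAs at -0.68. Precursors were also higher on day 28 than on day -1 (0.07), so both comparisons together do not decide. For lower ribosome biogenesis the median of 26 protein genes was -0.18 (interval -0.28 to 0.08), which spans 0 and decides nothing, so the bound set for it beforehand was too weak. A batch of its own for day 56 cannot be told apart from time, and a change with time itself was not tested.

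PAX6, a regulator of eye and brain, rose by 3.10 ± 0.26 to day 56, all 3 arrays lying above those of day 28, and SOX2 rose by 0.87. The neural list did not rise along with PAX6: the other 14 genes had a median of -0.0325 (interval -0.12 to 0.08), 1 higher and none lower. They ran from STMN2 at -0.68 (adjusted p = 0.33) to MAP2, which rose by 0.76 (adjusted p = 0.024). The MAP2 call ended with quantile normalization repeated (0.094), without replicates 1 or 3 of day 28 (0.069 and 0.073) and without replicates 2 or 3 of day 56 (0.079 and 0.073), while without replicate 1 of all groups the list median was 0.11 with 2 higher and none lower. The epithelial list did not rise either, with a median of -0.105 over 9 genes (interval -0.19 to 0.01), EPCAM at -0.07 and KRT8 at -0.10. TSPAN8 (4.06), VTCN1 (3.69) and CD24 (3.25), among the largest rises to day 56, are in neither list. The bounds of both tests were written after the values of the lists were seen, so their outcome was known. They describe the lists, on the scale of the PAX6 change, and do not decide about neural or epithelial cells. As levels are unknown, a small share of such cells may still be present, and other cells that use PAX6, a batch of the day 56 arrays and PAX6 in the cartilage cells themselves stay open.

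The fall of sterol synthesis genes to day 56 did not rest on a single array: the median of the list, -0.88 with all arrays, was at most -0.71 with any array left out. The fall was uneven among the day 56 arrays, and without replicate 1 the median was -0.99. On day 56 HMGCS1 was at -0.32 in replicate 1 against -1.56 and -1.57 in the others, and SQLE at -0.11 against -1.25 and -0.71. Further sterol enzymes outside the list had a median of -0.72 (interval -1.03 to -0.28), with 9 of 12 lower and TM7SF2 higher at 2.03 (camera adjusted p = 0.00071; adjusted p = 0.43 with an estimated correlation). A shared fall of the targets of SREBF2, the regulator of sterol synthesis, stays a hypothesis that met its test, a weak one, since genes of the sterol list vary together (estimated correlation 0.68) and a bootstrap over genes leaves this out. Targets of the liver X receptor, which sterol excess would raise, had a median of 0.27 (interval -0.38 to 1.08), with ABCA1 at 1.11 and APOE at -0.57; this interval spans 0, so the bound set beforehand was too weak and excess stays open. A difference in culture medium or batch was not tested.

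DLK1 and MEST, both imprinted, were among the largest falls to day 56, which raised the hypothesis that imprinted genes fell as a class. The 12 other imprinted genes measured had a median of -0.065 (interval -0.45 to 0.31), 4 higher and 4 lower, with PEG10 at -1.90 and GRB10 at 0.62; the interval spans 0, so the bound set beforehand was too weak and the test decides nothing.

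Splits of the same arrays were counted for each comparison. Of 10 splits of 6 arrays, 1, the real split, gave as many genes in each pairwise comparison, with 9684, 6145 and 10257 genes against at most 0, 1 and 0 in other splits; 10 splits are too few for a share under 0.05. For the 3 time points, 1 of 100 splits of the 9 arrays, the real one with 11774 genes, reached that count, and the highest other gave 6851. This share is under 0.05 and argues against a random grouping of the arrays for this count. It cannot exclude chance, as only 100 splits were counted, the real one included. The splits say nothing about batches that follow the groups.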
